A study of Caenorhabditis elegans with 6 samples.

How the data were processed

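RNA from a small set of sensory neurons was compared with RNA from whole Caenorhabditis elegans larvae on 1-colour Affymetrix C. elegans expression arrays. Per the labels, the neuronal RNA was poly(A) RNA recovered by mRNA tagging, in which PAB-1, which binds poly(A) tails, carried a FLAG epitope and was made in the PVD and OLL neurons from a ser-2 promoter fragment and pulled down with its bound mRNA. The reference was total RNA from whole animals. Both kinds of RNA came from larvae at the L3/L4 stage grown at 25 °C, and both were amplified with the same NuGEN kit before labelling. The type of RNA and the tissue therefore changed together between the groups. Each group had 3 arrays, 6 in all. The titles call the neuronal samples biological replicates and give only a number for the reference samples, so p-values measure the spread between these samples, which may in part be technical.

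The values analysed were the authors' deposited table of 1 value per probe set and array, summarised with RMA (background correction, quantile normalization and a robust summary of the probes), per the submitters' processing notes. The RMA software and its version are not given in the sources used here. The deposited values are taken to be on a log2 scale because they lay between 1.21 and 13.9. No label used here states the base, so every fold change rests on that reading. The scanner files were not used here, so background correction could not be repeated and scan dates were not examined. Probe set coordinates were not used here, because the genome build behind the array is not given in the sources used here.

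The table held 22625 probe sets. The 77 control probe sets were left out of the tests and 22548 were tested. Gene names came from the array's annotation table and were updated through a RefSeq gene table of assembly WBcel235, used for names only. Of the tested probe sets, 20766 had 1 gene name, 887 had several and 895 had none listed. For 20701 of the 20766 the name came from the RefSeq table, and for 65 the array's own name was kept. These covered 17118 genes. A gene with several probe sets was represented by the 1 with the highest mean over all 6 arrays. Of the 2981 genes with several probe sets, 938 had at least 1 called probe set, 183 had all of them called in the same direction and 1 had probe sets called in both directions. No sample column was left unused. Probe sets whose names end in _s_at or _x_at can match several transcripts, so values of near-identical families (major sperm proteins, collagens, histones) are uncertain for the single gene.

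Differences were computed as PVD and OLL minus whole animal with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all 22548 probe sets. A probe set was called at an adjusted p under 0.05, two-sided. Errors beside fold changes are limma's moderated standard errors (SE). The number of arrays limits the precision. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists with at least 3 measured genes, and again with an estimated correlation and with fry. The fry test asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Beside each count over all probe sets stands the count adjusted over the list alone. A background level was set on each array as the 95th percentile of 32 control probe sets for bacterial and yeast transcripts, which have no target in the samples. Where all 3 arrays of a group lay below that level, the fold is given as "at least", computed against the level, and no fold is given where this came to under 1.

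The genes named were chosen by a rule fixed before the data were examined. It took 12 genes in every case (pab-1, ser-2, mec-3, unc-86, F49H12.4, des-2, deg-3, eat-4, unc-119, rab-3, unc-54, vit-2), the 10 genes with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap between groups, and from each gene list with a called change up to 3 called members in the majority direction and 1 in the other. It also took 2 rises and 2 falls among genes known only by a clone name. A list with a called change was read as a list with at least 1 called member. The rule gave 109 genes, and the text does not name all of them. Some of those not named lost their calls more often with 1 array left out than the list member that is named. Among glial genes, lin-26 lost its call in 4 and lit-1 in 6 of 6 such runs, against 1 for itx-1. Other genes are named as chosen after their values were seen.

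The code was tested on simulated data for the comparison of PVD and OLL with whole animal. On 22548 simulated probe sets with the real means and residual spreads, 50 probe sets each were changed by 1, -1, 2 and -2 on the log2 scale. The share recovered in the right direction was 2% at 1, 4% at -1, 54% at 2 and 60% at -2, and 4 of 64 calls were false. Far fewer probe sets were changed in the simulation than the 3063 called in the data. The adjusted threshold was therefore harder to pass in the simulation, and these shares do not measure recovery in the data.

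Alternatives fixed in advance were quantile normalization repeated, centring on array medians or on proteasome subunit genes, cyclic loess, filters on dim probe sets, the replicate number as a block, each array left out in turn, a mean-variance trend with robust moderation, array quality weights, stricter thresholds, limma's treat, other ways to represent a gene, leaving out probe sets ending in _s_at or _x_at, and other list tests. Leaving out replicate 3 of both groups, a filter on the bacterial and yeast controls and centring on the bioB and bioC hybridisation controls were added after seeing the data. The amounts of these controls relative to the RNA are not given in the sources used here. Tables were joined with Python 3.11.15 and pandas 2.3.3 (numpy 2.4.6), and plots were drawn with matplotlib 3.10.9.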

Results

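Transcript levels in RNA pulled down by a tag made in the PVD and OLL neurons were compared with those of the whole animal in L3/L4 larvae. PVD neurons are highly branched mechanical and thermal nociceptors that lie along the body, and OLL neurons are sensory neurons of the head. Poly(A) RNA was pulled down from these cells through a tagged poly(A) binding protein and hybridised on 3 arrays, and total RNA of whole larvae was hybridised on another 3. Array medians were 3.86, 3.89 and 3.72 on the log2 scale for PVD and OLL replicates 1, 2 and 3, and 3.61, 3.59 and 3.67 for the whole animal replicates. Between 73.2% and 77.5% of probe sets exceeded the no-target background on the PVD and OLL arrays, and between 53.4% and 65.04% did on the whole animal arrays. Across probe sets, which are not independent replicates, the correlation was 0.988 between PVD and OLL replicates 1 and 2 and 0.954 and 0.961 between each of these and replicate 3. In the whole animal group, replicates 1 and 2 correlated at 0.973, and replicate 3 correlated with them at 0.938 and 0.940. Between groups the correlation ranged from 0.871 to 0.926.

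The comparison asked which transcripts were enriched in the RNA pulled down from the PVD and OLL neurons. How much RNA of other cells came down with it was not tested. The body wall muscle gene unc-54 had means of 10.68 in the PVD and OLL group and 10.21 in the whole animal. A rise therefore does not by itself place a transcript in these neurons. The largest rises were in deg-3 and des-2, which encode nicotinic acetylcholine receptor subunits and share an operon. deg-3 rose by 4.27 ± 0.38 (log2, SE, n = 3 arrays per group, adjusted p = 0.00402), a 19.3-fold difference, and des-2 by 4.09 ± 0.23 (adjusted p = 0.00205), a 17.03-fold difference. Genes known only by clone names aside, the next largest were dpy-8, a cuticle collagen, at 3.78 ± 0.37, lgc-12, a ligand-gated ion channel subunit, at 3.53 ± 0.35, and peb-1, a DNA-binding protein of the pharynx, at 3.49 ± 0.40. The rule also took drh-2 (3.42), myrf-1 (3.33), clec-180 (3.29), pha-4 (3.23) and ugt-50 (3.21). Second probe sets of deg-3, des-2, peb-1 and pha-4 rose by 3.06, 3.34, 2.05 and 1.87, and those of ugt-50 differed by 1.199 (adjusted p = 0.067) and 0.44 (adjusted p = 0.16). With the same exception, the largest falls were in vit-6, a yolk protein gene, at -3.66 ± 0.88, mtre-1 at -3.43 ± 0.53, and the collagen genes col-129 at -3.41 ± 0.52 and col-137 at -3.39 ± 0.40. They were followed by dct-5 (-3.32), col-106 (-3.31), pals-26 (-3.30) and col-81 (-3.19). Of the genes known only by clone names, Y65B4BL.1 (3.74) and H40L08.2 (3.57) rose and F57C2.4 (-3.68) and F45E4.5 (-2.84) fell. A second probe set of Y65B4BL.1 rose by 1.597, and that of vit-6 differed by -2.78 (adjusted p = 0.0513). With single arrays left out, calls were lost for vit-6 in 4 of 6 runs (adjusted p up to 0.0816), clec-180 in 4 (0.118), F57C2.4 in 5 (0.105) and Y65B4BL.1 in 2 (0.0637), and without PVD and OLL replicate 2 for pha-4 (0.0515), col-106 (0.0591) and pals-26 (0.0559).

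Over all probe sets, 2099 were higher and 964 lower in the PVD and OLL samples, 13.6% of those tested. At least 2-fold differences numbered 1786 higher and 691 lower. On 40.5% of probe sets the arrays of both groups did not overlap, against 10% by chance. By gene, 1387 were higher and 797 lower. The direction split depended on the scaling: 68.5% of calls were higher with the deposited values, 54.2% after repeated quantile normalization, 52.6% after cyclic loess, 43.1% with arrays centred on their medians, 80.2% with centring on proteasome genes and 99.1% with centring on the bioB and bioC controls, the last chosen after seeing the data. The median log2 difference of all probe sets was -0.03, and centring moved it by -0.20 (medians), 0.13 (proteasome genes) and 1.07 (bioB and bioC controls), so directions given here are relative to the deposited scale. The amounts of the bioB and bioC controls relative to the RNA are not given in the sources used here, so that centring shows how far directions rest on the scale and does not measure RNA amount. Without PVD and OLL replicate 2, the counts fell to 577 higher and 208 lower, without PVD and OLL replicate 1 to 902 and 281, without whole animal replicate 1 to 1247 and 460, and without whole animal replicate 2 to 1108 and 510. With replicate 3 of both groups left out, added after seeing the data, they were 3300 and 1842.

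Markers of the targeted neurons were higher as a group. Of 15 measured PVD and OLL markers, 8 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.89 (camera adjusted p = 7e-07, and adjusted p = 0.0673 with an estimated correlation). Besides deg-3 and des-2, mec-3, a LIM homeobox gene needed for PVD branching, rose by 2.23 ± 0.31 (adjusted p = 0.00741) and unc-86, a POU homeobox gene that acts upstream of mec-3, by 1.36 ± 0.21 (adjusted p = 0.00948, and 0.0515 without PVD and OLL replicate 2). asic-1, a DEG/ENaC channel subunit, was 0.89 ± 0.23 higher (adjusted p = 0.0434), a call lost in 6 of 6 runs with 1 array left out (adjusted p up to 0.125). Some markers did not pass the test. The tyramine receptor gene ser-2, whose promoter fragment drove the tag, had means of 2.91 in the PVD and OLL group and 2.19 in the whole animal (adjusted p = 0.202), and the PVD marker F49H12.4 had means of 2.75 and 2.72 (adjusted p = 0.945). The vesicular glutamate transporter gene eat-4 differed by 0.01 ± 0.25 (adjusted p = 0.988). All 3 had mean signals under 3 in both groups. The no-target background was between 2.28 and 2.44 on the PVD and OLL arrays and between 2.95 and 3.43 on the whole animal arrays. F49H12.4 and eat-4 exceeded it on 3 PVD and OLL arrays and ser-2 on 2, while on the whole animal arrays eat-4 exceeded it on replicate 3 and the others on none. The other probe set of eat-4 differed by 0.45 (adjusted p = 0.205).

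Genes known to act in PVD dendrite formation were higher, although several entered the literature through follow-up of PVD expression profiles, so their count is not independent evidence. Of 25 genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone). The median log2 fold change was 1.36 (camera adjusted p = 3.47e-09, and adjusted p = 0.0622 with an estimated correlation). The dendritic receptor gene dma-1 rose by 2.11 ± 0.32 (adjusted p = 0.00904) and hpo-30, which encodes a claudin-like protein, by 1.98 ± 0.37 (adjusted p = 0.0156, lost in 3 of 6 runs with 1 array left out, up to 0.0537). mec-3, unc-86 and egl-46 belong to both this list and that of the markers. The pan-neuronal, guidance and transcription factor lists also share members with it, so these lists are not separate evidence.

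**Figure D1:**
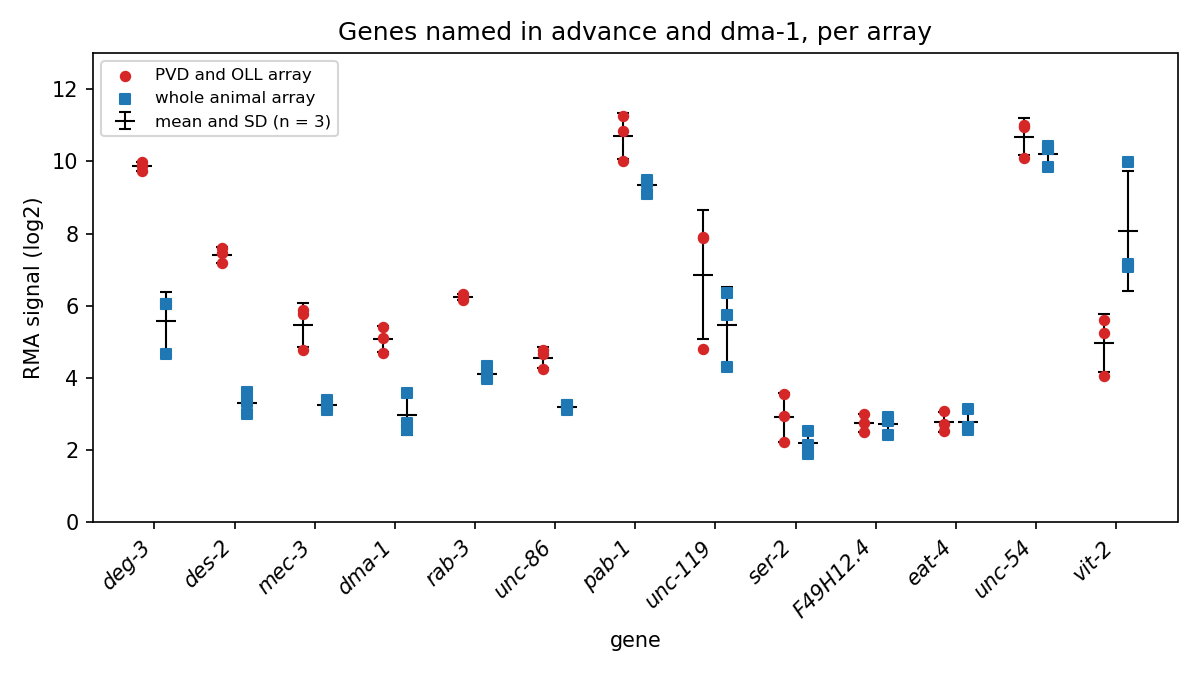
RMA signal on the log2 scale (vertical axis) of 13 genes on each of the 3 PVD and OLL arrays (circles) and 3 whole animal arrays (squares), with the mean and SD of each group in black. deg-3 had a mean of 9.86 in the PVD and OLL group and 5.59 in the whole animal, while F49H12.4 and eat-4 had means under 3 in both.

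Pan-neuronal genes of synapses and vesicles were higher: of 49 genes 23 rose and 0 fell (32 and 0 adjusted over the list alone). The median of these genes was 1.04 (camera adjusted p = 2.83e-12, and adjusted p = 0.228 with an estimated correlation). The SNARE gene ric-4 rose by 2.27 ± 0.34, the clathrin adaptor gene unc-11 by 2.24 ± 0.21 and the vesicle GTPase gene rab-3 by 2.12 ± 0.19. Their adjusted p-values were 0.00858, 0.00402 and 0.00402, and the other probe set of rab-3 differed by 0.63 (adjusted p = 0.238). Of the other probe sets of unc-11, 1 differed by 0.03 (adjusted p = 0.943). unc-119 was not called (1.38 ± 0.88, adjusted p = 0.309); its signal was 7.90 and 7.88 on PVD and OLL replicates 1 and 2 and 4.80 on replicate 3. The list median relative to the whole animal mean was 1.17, 1.21 and 0.69 on PVD and OLL replicates 1, 2 and 3. Of 19 touch receptor neuron genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone). Across the list the median was 0.78 (camera adjusted p = 2.08e-05, and adjusted p = 0.228 with an estimated correlation). Without probe sets ending in _s_at or _x_at it was 0.28 (adjusted p = 0.0761). The genes that rose included mec-17, a tubulin acetyltransferase gene, at 2.36 ± 0.35. They also included deg-3, des-2, mec-3 and unc-86, which the list of PVD and OLL markers holds as well.

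Axon guidance and adhesion receptors showed 15 rises and 0 falls among 52 genes (15 and 1 adjusted over the list alone). The list median was 0.65 (camera adjusted p = 4.25e-06, and adjusted p = 0.0673 with an estimated correlation). The cadherin gene cdh-10 rose by 2.52 ± 0.18 (other probe set 0.67, adjusted p = 0.274), the neurexin gene nrx-1 by 2.22 ± 0.35 and the contactin gene rig-6 by 2.16 ± 0.36, the last with an adjusted p of 0.0537 without PVD and OLL replicate 2. Of 30 tubulin and microtubule motor genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone). The median log2 fold change was 0.64 (camera adjusted p = 0.00446, and adjusted p = 0.147 with an estimated correlation), and 0.40 without probe sets ending in _s_at or _x_at (adjusted p = 0.275). The kinesin gene klp-4 rose by 2.03 ± 0.21, and mec-12, an alpha-tubulin gene, by 1.86 ± 0.44 with a call lost in 4 of 6 runs with 1 array left out (adjusted p up to 0.119). Of 18 glutamate receptor subunit genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone). The median of these genes was 0.33, and 0.52 without whole animal replicate 1 (camera adjusted p = 0.00839 with all arrays, and adjusted p = 0.165 with an estimated correlation). glr-4 was at least 4.36-fold higher (adjusted p = 0.00402), with other probe sets at 0.95 and 0.44. avr-14, a glutamate-gated chloride channel gene, rose by 2.25 ± 0.35, while its other probe set, with means under 3 in both groups, differed by -0.02 ± 0.23 (adjusted p = 0.963).

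Homeobox and other neuronal transcription factor genes had 17 rises and 0 falls among 102 (18 and 0 adjusted over the list alone). Across the list the median was 0.15, and -0.05 with arrays centred on their medians (camera adjusted p = 0.0405, and adjusted p = 0.165 with an estimated correlation). Its list call was lost without PVD and OLL replicate 2, whole animal replicate 2 or whole animal replicate 3 (adjusted p up to 0.0637), and without probe sets ending in _s_at or _x_at (0.104). The median was 0.08 without PVD and OLL replicate 2. After mec-3 the largest rises were ceh-34 at 2.12 ± 0.36 (adjusted p = 0.0122, and 0.0514 without PVD and OLL replicate 2) and ceh-37 at 2.08 ± 0.44 (adjusted p = 0.0234, lost in 3 of 6 runs with 1 array left out, up to 0.0931), whose other probe set differed by 0.46 (adjusted p = 0.163). Of 42 cilium and intraflagellar transport genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone). The list median was 0.24 (camera adjusted p = 0.0188, lost without PVD and OLL replicate 1 at 0.0721, and adjusted p = 0.341 with an estimated correlation). The list was not called with fry (adjusted p = 0.0766), without probe sets ending in _s_at or _x_at (0.104) or without the dimmest 25% of probe sets (0.134). Its median was 0.15 without PVD and OLL replicate 1 or 2 and 0.39 without replicate 3. The RFX factor gene daf-19 was at least 1.99-fold higher (adjusted p = 0.0076) and the transport gene osm-1 rose by 1.22 ± 0.21 (0.0592 without PVD and OLL replicate 2), while the dynein light intermediate chain gene xbx-1 fell by 1.13 ± 0.24, a call lost in 5 of 6 such runs (adjusted p up to 0.0869). Mean signals of xbx-1 were 2.29 in the PVD and OLL group and 3.42 in the whole animal, near the no-target background. The no-target controls were themselves lower in the PVD and OLL samples (median -0.50).

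Other channel and receptor lists had few called members, but calls were few over all genes as well (1387 higher and 797 lower of 17118). Camera did not call them on the deposited values, while fry called the DEG/ENaC, TRP and nicotinic lists (adjusted p = 7.63e-05, 0.00485 and 0.00225), as did camera after cyclic loess (0.019 for each). Of 29 DEG/ENaC subunits, 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.151), with del-5 up by 2.11 ± 0.18. Of 16 TRP channels, 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.138), with trp-2 up by 2.11 ± 0.29. Of 28 nicotinic receptor subunits, deg-3 and des-2 were the 2 that rose, and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.15). Of 67 potassium channels, 9 rose and 1 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.221). kcnl-4, of the small-conductance calcium-activated class, rose by 2.98 ± 0.38, and kvs-4 was lower by -0.83 ± 0.22 (adjusted p = 0.0449, lost in 5 of 6 runs with 1 array left out, up to 0.127), but 0.25 higher with centring on the bioB and bioC controls. Mean signals of kvs-4 lay near background, at 2.49 in the PVD and OLL group and 3.32 in the whole animal.

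Few members of the lists for other neuron classes were called. Of 33 markers of other sensory neurons, 1 rose and 1 fell (0 and 1 adjusted over the list alone). The median log2 fold change was -0.27 (camera adjusted p = 0.0882), and 0.81 with centring on the bioB and bioC controls. Only 17 of the 33 had a mean above the no-target background in at least 1 group, so much of the list was read near background. Camera called this list lower without the dimmest 25% of probe sets (-0.62, adjusted p = 0.0377) and without whole animal replicate 3 (-0.31, 0.0375). The member that fell was the guanylate cyclase gene gcy-34, with means near background (2.60 in the PVD and OLL group and 3.72 in the whole animal). It differed by -1.12 ± 0.23 (adjusted p = 0.0203, lost in 4 of 6 runs with 1 array left out, up to 0.0871). The member that rose, ceh-36, lay at background in the whole animal (adjusted p = 0.0492, lost in 5 of 6 such runs, up to 0.139). Of 8 cholinergic markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.506), with a median of -0.01 and a mean of 0.13. That member, unc-3, was at least 1.58-fold higher (adjusted p = 0.0257, lost in 4 of 6 runs with 1 array left out, up to 0.0921). The cholinergic markers unc-17 and cha-1 had no probe set of their own and were not among the 8. Of 6 GABAergic markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.313), namely the glutamate decarboxylase gene unc-25 at 1.26 ± 0.25 (adjusted p = 0.0204, lost in 3 of 6 runs with 1 array left out, up to 0.0892). Among 7 dopaminergic and serotonergic markers, limma called 0 in either direction, also adjusted over the list alone and at an unadjusted p under 0.05, with a median of -0.11 (camera adjusted p = 0.76, fry adjusted p = 0.438).

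Among 25 FMRFamide-like genes limma called 0 in either direction, also adjusted over the list alone, with 5 higher and 1 lower at an unadjusted p under 0.05 and a median of 0.31 (camera adjusted p = 0.138, and 0.0384 without PVD and OLL replicate 3; fry adjusted p = 0.215). Of 61 other neuropeptide-like genes, 9 rose and 4 fell (16 and 5 adjusted over the list alone), and the median was 0.31 (camera adjusted p = 0.0626). Camera called it higher without probe sets ending in _s_at or _x_at (0.51, adjusted p = 0.0225), with arrays centred on their medians (0.10, 0.0269) and without PVD and OLL replicate 3 (0.0479), whole animal replicate 1 (0.0248) or whole animal replicate 2 (0.0345). nlp-81 was at least 6.87-fold higher (adjusted p = 0.00205), nlp-50 rose by 3.14 ± 0.46 and nlp-25 fell by 2.11 ± 0.26, the last call being lost under 1 of 5 other scalings. Of 24 insulin-like genes, 4 rose and 1 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.76), and the list had a median of -0.17 with a mean of 0.18. ins-35 rose by 2.02 ± 0.31 and daf-28 by 1.81 ± 0.29.

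Markers of muscle, gut and epithelia did not fall together. Of 30 body wall muscle genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone). The median of these genes was 0.06 (camera adjusted p = 0.313). The myosin gene myo-3 was 1.05 ± 0.20 higher (adjusted p = 0.0188, lost in 3 of 6 runs with 1 array left out, up to 0.0869), and unc-54, another myosin gene, differed by 0.47 ± 0.31 (adjusted p = 0.314). The ryanodine receptor gene unc-68 was lower by -0.96 ± 0.24 (adjusted p = 0.0365, lost in 5 such runs, up to 0.136), but 0.11 higher with centring on the bioB and bioC controls and 0.12 higher without probe sets ending in _s_at or _x_at. Of 18 pharyngeal genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.28), the forkhead gene pha-4. Of 51 intestinal genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.155), with a median of 0.26 and a mean of 0.01. The cathepsin B-like protease genes cpr-1 at 2.09 ± 0.19 and cpr-5 at 1.99 ± 0.27 rose, whereas the yolk protein gene vit-2 fell by 3.09 ± 0.79 (adjusted p = 0.0421, lost in 5 of 6 runs with 1 array left out, up to 0.112).

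Of 54 hypodermal and seam genes other than collagens, 10 rose and 5 fell (14 and 8 adjusted over the list alone). Across the list the median was 0.41 (camera adjusted p = 0.0626). The list was called higher by camera with arrays centred on their medians (0.21, adjusted p = 0.0257), with the mean of all probe sets of a gene (0.39, 0.0278) and without PVD and OLL replicate 3 (0.0479), whole animal replicate 1 (0.0209) or whole animal replicate 2 (0.0345). dpy-20 rose by 1.86 ± 0.21, and the hedgehog-related genes wrt-2 and grd-5 changed by 2.59 ± 0.45 (adjusted p = 0.061 without PVD and OLL replicate 2) and -1.84 ± 0.24 (lost under 1 of 5 other scalings). Of 18 glial genes, 3 rose and 0 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.192, and 0.0437 after repeated quantile normalization), with itx-1 at 1.34 ± 0.22 (0.0591 without PVD and OLL replicate 2). Of 9 coelomocyte genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.294), namely ceh-34, which the transcription factor list also holds. Of 17 excretory canal and gland genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone). The list median was 0.28 (camera adjusted p = 0.0405, lost without whole animal replicate 2 or 3, up to 0.141, and adjusted p = 0.224 with an estimated correlation). Its call was also lost after repeated quantile normalization (0.10, adjusted p = 0.0865) and cyclic loess (0.08, 0.135), without the dimmest 25% of probe sets (0.139) and with array quality weights (0.066). The lipocalin gene lpr-1 was at least 4.94-fold higher (adjusted p = 0.00904). Of 63 germline and oogenesis genes, 1 rose and 2 fell (1 and 0 adjusted over the list alone), and the median was -0.14 (camera adjusted p = 0.294). Camera called the germline list lower after cyclic loess (-0.41, adjusted p = 0.00271), after repeated quantile normalization (-0.40, 0.00496) and without the dimmest 25% of probe sets (-0.15, 0.0377), while its median was 0.93 with centring on the bioB and bioC controls. atx-2 rose by 1.85 ± 0.19 (other probe set 0.35, adjusted p = 0.36), and the yolk receptor gene rme-2 was lower by -2.24 ± 0.57 (adjusted p = 0.0405, lost in 6 of 6 runs with 1 array left out, up to 0.0924).

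**Figure D2:**
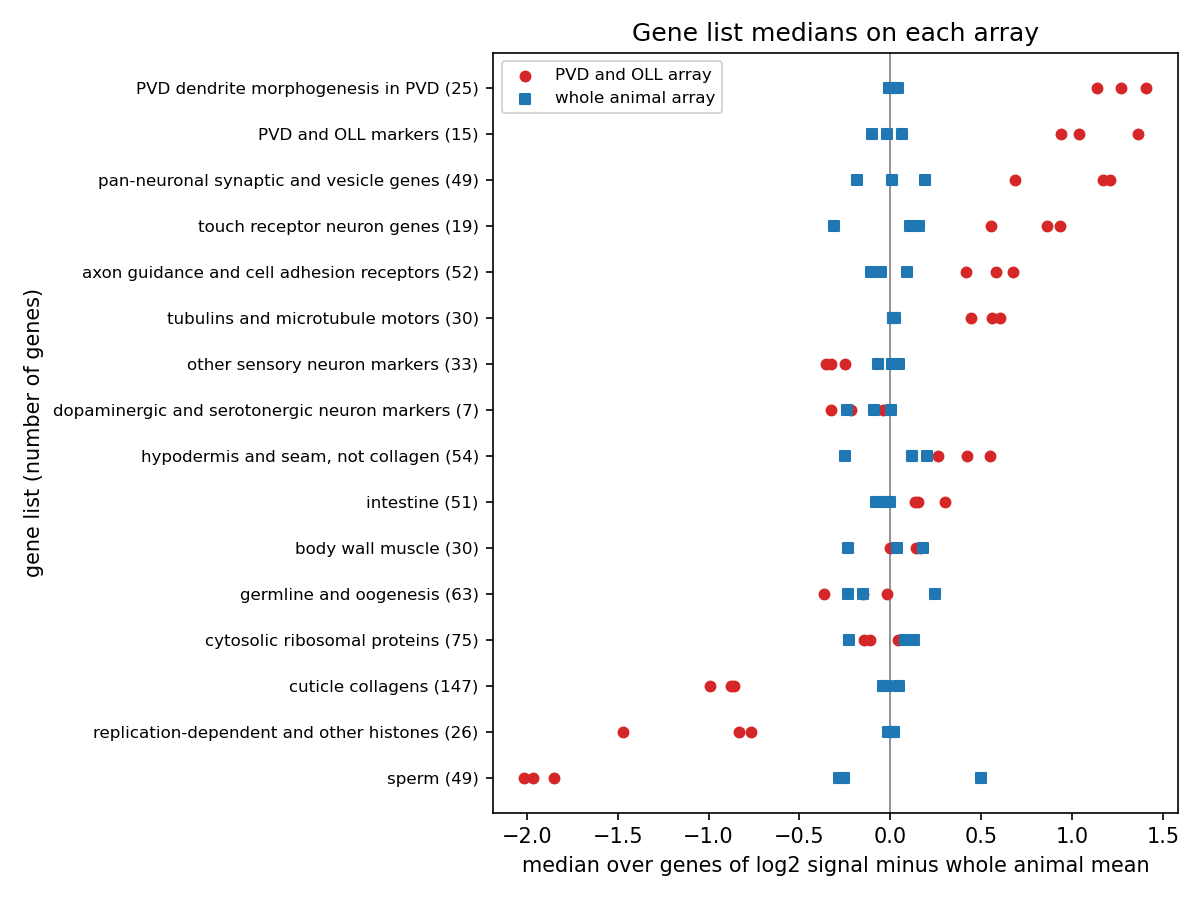
Median over the genes of a list of the log2 signal minus the whole animal mean (horizontal axis) for 16 gene lists (vertical axis, with the number of genes), on each PVD and OLL array (circles) and whole animal array (squares). The sperm list lay at -1.96, -1.85 and -2.01 on the PVD and OLL arrays, and the body wall muscle list at 0.16, 0.14 and 0.00.

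Cuticle collagens, sperm genes and histones were lower on the deposited scale, and the collagen and histone medians turned positive with centring on the bioB and bioC controls. These controls differed most between groups (median -1.23), while the other 8 hybridisation controls (bioD and cre) had a median of -0.31. A shift of that size was thus not shared by all hybridisation controls. With that centring camera, which compares a list with the other genes, still placed collagens and histones lower. Of 147 collagens, 69 fell and 8 rose (84 and 16 adjusted over the list alone). The median log2 fold change was -0.89, and 0.19 with centring on the bioB and bioC controls (camera adjusted p = 1.24e-12, and adjusted p = 0.0622 with an estimated correlation). The collagen dpy-8, up by 3.78, stood at the other end from col-129 and col-137. Of 49 sperm genes, 34 fell and 0 rose (41 and 0 adjusted over the list alone). The median of these genes was -1.93 (camera adjusted p = 5.08e-20, and adjusted p = 0.224 with an estimated correlation). Over the 22 alternatives this median ranged from -2.13 to -0.71. The major sperm protein genes msp-49 and msp-50 fell by 2.60 ± 0.37 and 2.59 ± 0.38, on probe sets that near-identical copies can share. Whole animal replicate 3 had more sperm signal than the other reference arrays (list medians of 0.50, against -0.28 and -0.25, relative to the group mean). Of 26 histone genes, 13 fell and 1 rose (15 and 2 adjusted over the list alone). Across the list the median was -1.06 (camera adjusted p = 0.000164, and adjusted p = 0.256 with an estimated correlation). That median was -0.15 without probe sets ending in _s_at or _x_at (adjusted p = 0.995) and 0.01 with centring on the bioB and bioC controls. his-67 fell by 2.202 ± 0.394 (adjusted p = 0.0139), and the linker histone gene his-24 was 1.72 ± 0.39 higher (adjusted p = 0.0298, lost in 5 of 6 runs with 1 array left out, up to 0.0983).

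**Figure D3:**
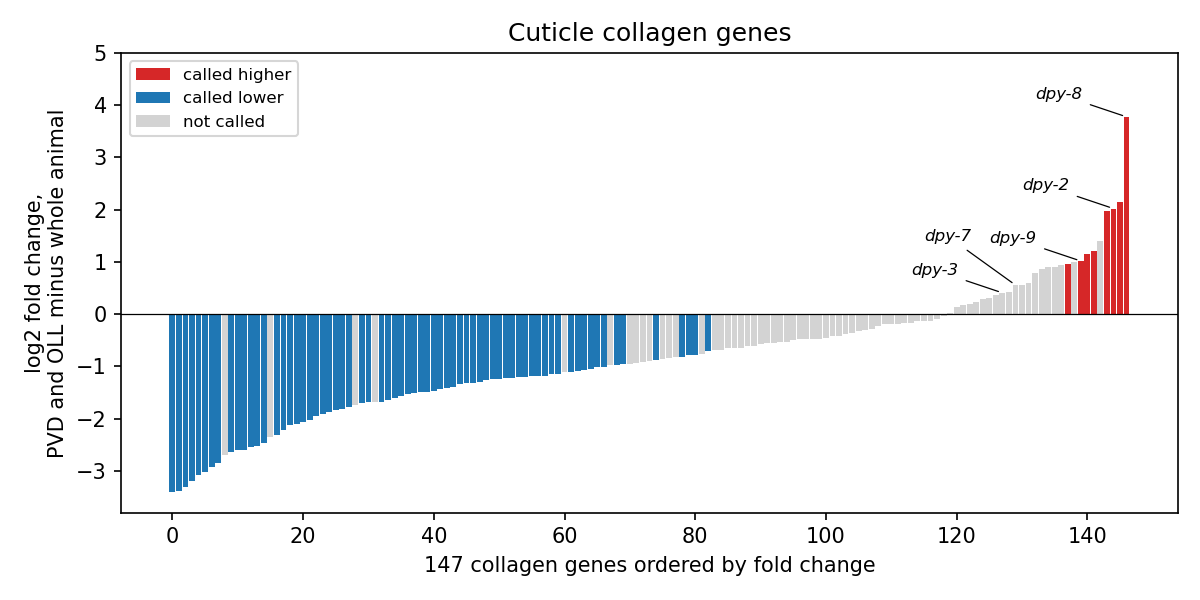
Log2 fold change, PVD and OLL minus whole animal (vertical axis), of the 147 measured cuticle collagen genes ordered by that value (horizontal axis), coloured by whether the gene was called higher, lower or not called. The labelled genes are dpy-2, dpy-3, dpy-7, dpy-8 and dpy-9. Of all 147, 69 were lower and 8 higher on the deposited scale. The list median turned from -0.89 to 0.19 with centring on the bioB and bioC controls, while camera still placed the list below the other genes.

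Few genes of general cell functions were called. Of 75 ribosomal protein genes, 2 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.492), with a median of -0.07. Camera called the ribosomal list higher after cyclic loess (0.16, adjusted p = 0.00365) and lower without replicate 3 of both groups (-0.20, adjusted p = 0.00295). The 2 genes that rose were rpl-31 at 1.06 ± 0.21 and rpl-7A at 0.82 ± 0.21 (lost in 2 and 6 of 6 runs with 1 array left out, adjusted p up to 0.0764 and 0.128). Of 31 proteasome genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone), and the median was -0.11 (camera adjusted p = 0.309). The list was called lower by camera after cyclic loess (-0.33, adjusted p = 0.00409) and repeated quantile normalization (-0.31, 0.00603), while its median was 0.96 with centring on the bioB and bioC controls. The members that fell were pbs-4 at -1.28 ± 0.22 and pas-5 at -1.24 ± 0.20 (adjusted p up to 0.0619 and 0.0561 without PVD and OLL replicate 2). Of 41 respiratory chain genes, 0 rose and 3 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.891), with a median of 0.02 and a mean of -0.03. The ATP synthase subunit gene asb-1 fell by 1.33 ± 0.19, a call lost under 1 of 5 other scalings, and differed by -0.25 with centring on the bioB and bioC controls. The complex I genes nuo-6 and nuo-2 were lower by -0.99 and -0.72 but 0.08 and 0.35 higher with that centring, with calls lost in 3 and 6 of 6 runs with 1 array left out (adjusted p up to 0.11 and 0.173). Of 23 heat shock and stress genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.181), and 1 of these was hsp-4, an endoplasmic reticulum chaperone gene, at 0.97 ± 0.20 (adjusted p = 0.021, lost in 4 of 6 runs with 1 array left out, up to 0.0869). Of the 2 poly(A) binding protein genes, too few for a list test, 1 rose and 0 fell (2 and 0 adjusted over the list alone). This was pab-1, the gene of the tagged protein, at 1.36 ± 0.33 (adjusted p = 0.0351, lost in 5 of 6 such runs, up to 0.123), and its other probe sets differed by 0.92 ± 0.23 (adjusted p = 0.0408) and 0.51 ± 0.26 (adjusted p = 0.213). The probe set that stood for pab-2 differed by 0.54 ± 0.22 (adjusted p = 0.147), while its other probe sets differed by 1.57 ± 0.32 (adjusted p = 0.0203), 1.45 ± 0.25 (adjusted p = 0.0122) and 0.10 ± 0.23 (adjusted p = 0.781).

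Of the 35 lists tested, 13 were called, 10 higher and 3 lower. With an estimated correlation camera called 0 (smallest adjusted p = 0.0622; 7 at an unadjusted p under 0.05), and fry called 19. These were 12 of the 13, without the cilium list, and the DEG/ENaC, TRP, nicotinic, other sensory neuron (adjusted p = 0.0239), intestine (0.0161), proteasome (0.0161) and heat shock (0.0131) lists. Dim probe sets were lower in the PVD and OLL samples than bright ones: the median log2 difference was -0.25 in the dimmest 25% of probe sets, -0.06 in the next 25%, 0.35 in the 25% above these and 0.18 in the brightest 25%, and the 32 no-target controls had a median of -0.50.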

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

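The tests of the 3 patterns weighed here were chosen after the results were seen, while the counts over other splits of the arrays were set in advance. Of 27 worm control probe sets, kept out of the comparison, 2 were called higher in the PVD and OLL samples (0 of the 32 no-target controls were) and 7 lower (median of all -0.26). The probe set for the 3' end of catalase was 0.65 higher on the log2 scale (limma, adjusted p = 0.0296 over the controls) and the middle probe set of Gapdh was 0.85 higher (adjusted p = 0.0296), while the 5' end of catalase was lower by -0.95 (adjusted p = 0.0335). Single outlying arrays were not tested for in groups of 3.

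With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. The real split alone (1 of 10) gave as many calls for each count: 2099 higher, 964 lower, 1786 at least 2-fold higher and 691 at least 2-fold lower, while the highest count of the other splits was 0 with limma. At an unadjusted p under 0.05 the real split gave 4208 higher and 3037 lower, and the highest other split gave 1049.

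Sperm genes and collagens were lower on the deposited scale (collagens not with centring on the bioB and bioC controls, median 0.19) while 10 of 54 other hypodermal genes rose and 5 fell. A loss of non-neuronal RNA of every tissue would lower body wall muscle genes about as much as sperm genes (median -1.93), but their median was 0.0575, with an SD of 0.54 between members. A loss of hypodermal RNA would lower other hypodermal genes with the collagens (median -0.89), but their median was 0.41, with an SD of 0.999 between members. These genes include the molting regulator nhr-23 (1.65 higher), so a difference in molt phase could move them as well. Their median therefore cannot exclude a loss of hypodermal RNA. A difference in age or molt phase between the animals may contribute: 5 collagens known to be transcribed early in each molt cycle (dpy-2, dpy-3, dpy-7, dpy-8, dpy-9) lay 1.96 above the other collagens in their medians (two-sided permutation test over genes, p = 0.00169), although dpy-8 had been seen before the set was written. That p-value treats genes as independent, although collagens can share probes, and does not measure the spread between arrays. The labels give both groups as L3/L4 and no finer age, so a difference in age or molt phase and a difference between tissues both stay open.

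Histone genes were lower on the deposited scale (not with centring on the bioB and bioC controls, median 0.00871) in the PVD and OLL samples, which were poly(A) RNA, while the reference was total RNA. Most core histone mRNAs lack a poly(A) tail, and the 6 measured H1 and H3.3-type histone genes, thought to carry one more often, lay 1.68 above the other 20 in their medians (two-sided permutation test over genes, p = 0.00569). That p-value treats genes as independent, although histone genes can share probes, and does not measure the spread between arrays. The RNA type may contribute. Fewer cells in S phase would lower the replication genes mcm-2 to mcm-7, whose median was 0.0153, but these went both ways (SD 0.59 between the 6 genes) and leave that open. Probe sets shared between near-identical copies also stay open, since the 5 core histone genes with probe sets of their own had a median of -0.0710 and ranged from -2.202 (his-67) to 2.24 (his-41). That median lay nearer the 0.35 of the 6 H1 and H3.3-type genes than the -1.33 of the other 20. The contrast therefore cannot separate the RNA type from shared probe sets.

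PVD and OLL replicate 3 had a pan-neuronal median of 0.69, against 1.17 and 1.21 on the other 2 arrays of its group. Dilution with RNA like that of the reference would also have brought its sperm genes nearer the reference, but their median there was -2.01, against -1.96 and -1.85. Dilution with RNA of the tagged animals themselves stays open, because the sperm level of those animals was not measured. A batch shared by the arrays numbered 3 would make both deviate together, but the correlation of their deviations across probe sets was -0.104. A different share of neurons among the tagged cells was not tested and stays open.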

How the results depend on the processing

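Centring on the bioB and bioC controls, leaving out replicate 3 of both groups and the filter on no-target controls were chosen after seeing the data; the cause of changes was not tested unless stated. All named genes were called except ser-2, F49H12.4, eat-4, unc-119 and unc-54. Most of the called named genes lost their call in at least 1 of the 6 runs with 1 array left out. Only 45 stayed called in all 6 of these runs, while 69 stayed called under all 5 other scalings. Of 13 called lists, 10 and 12 did. The lists of PVD and OLL markers, dendrite, pan-neuronal, guidance and adhesion, and sperm genes kept direction and call under 21 of 22 alternatives each, the exception being the estimated correlation. The size of the sperm fall was less stable, with medians from -2.13 to -0.71 over the alternatives. Adjusted p for histones ranged from 6.41e-08 to 0.995 and for intestine from 0.0161 to 0.805. For ser-2, F49H12.4 and eat-4, with mean signals under 3, the signal near background limits what could be detected. Signs changed for 65 results that were called neither here nor under the alternative.

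Counts higher and lower were 1192 and 1007 after repeated quantile normalization (1018 at least 2-fold higher) and 1195 and 1079 after cyclic loess (998 at least 2-fold higher). Centring on medians gave 1952 lower (1344 at least 2-fold), and centring on the bioB and bioC controls 10876 higher and 100 lower, all of them at least 2-fold. Array quality weights gave 4035 and 2767 (1078 at least 2-fold lower). Stricter thresholds gave 516 and 168 at an adjusted p under 0.01 and 1.5-fold, and 340 and 111 with treat, all of them at least 2-fold too. Without probe sets ending in _s_at or _x_at, where fewer were tested, 1186 and 600 were called (1016 and 419 at least 2-fold). Without replicate 3 of both groups they were 3300 and 1842 (1063 at least 2-fold lower). With 1 array left out, higher calls ranged from 577 to 2017, lower from 208 to 1222, at least 2-fold higher from 577 to 1763 and at least 2-fold lower from 208 to 863.

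With the replicate number as a block, 1224 probe sets were higher and 405 lower (404 at least 2-fold lower), the transcription factor list was not called (adjusted p = 0.05) and the hypodermal list was (0.0293). Deviations of same-numbered arrays correlated at -0.0513, -0.0651 and -0.104, which gave no sign of pairing. No PVD and OLL array had deviations that correlated best with those of the reference array of its own number. Weak pairing cannot be excluded, because replicate 3 stood apart in each group. Its deviations correlated with those of replicates 1 and 2 at -0.808 and -0.730 (PVD and OLL) and -0.700 and -0.678 (whole animal). By the values themselves, replicate 1 alone of the 3 correlated best with its own number.

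With an estimated correlation the medians do not change but calls were lost for PVD and OLL markers (median 0.89, adjusted p = 0.0673), dendrite genes (1.36, 0.0622), pan-neuronal genes (1.04, 0.228), guidance and adhesion (0.65, 0.0673), collagens (-0.89, 0.0622), sperm (-1.93, 0.224) and histones (-1.06, 0.256). With fry 12 of the 13 lists stayed called, the cilium list (0.0766) not, and 7 more were called, among them intestine (0.26, 0.0161). Without probe sets ending in _s_at or _x_at 8 of the 13 stayed called, and calls were lost for histones (median -0.15), touch receptor neuron (0.28), cilium (0.16), transcription factor (0.02) and tubulin and motor genes (0.40). The excretory list lost its call under 10 of 22 alternatives and the cilium and transcription factor lists under 6 each (adjusted p from 0.00611 to 0.224, 0.000711 to 0.341 and 2.6e-05 to 0.165). Centring on the bioB and bioC controls put the medians of body wall muscle at 1.13, intestine at 1.33, collagens at 0.19 and histones at 0.00871. It put ins-32, at least 1.44-fold lower on the deposited scale and below background on the PVD and OLL arrays, at 0.21, kvs-4 at 0.25, unc-68 at 0.11, nuo-6 at 0.0783 and nuo-2 at 0.35. unc-68 was 0.12 without probe sets ending in _s_at or _x_at, the ribosomal median 0.16 after cyclic loess and the transcription factor median -0.0529 with centring on medians. With centring on the bioB and bioC controls camera, which compares a list with the other genes, still placed collagens and histones lower. With centring on medians it still placed transcription factors higher. Leaving out 1 array, medians ranged from 0.80 to 1.07 for PVD and OLL markers, 1.25 to 1.37 for dendrite genes, 0.91 to 1.22 for pan-neuronal genes, 0.51 to 0.69 for guidance and adhesion, -0.95 to -0.84 for collagens, -2.06 to -1.65 for sperm, -1.25 to -0.82 for histones, -0.02 to 0.20 for body wall muscle and 0.21 to 0.27 for intestine.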

Other observations

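The families and genes in this part were chosen after seeing the data. Genes were grouped by the stem of their names into 233 groups of at least 8 measured genes, called families here. A shared stem does not by itself mean related sequences: the lin genes named below include a period homolog and a Hox gene. The unc family includes members of the pan-neuronal list such as unc-11. Each family was tested for called members in each direction with Fisher's exact test, adjusted over 466 tests. Over all 17118 genes, 1387 were higher and 797 lower. Families enriched among higher genes were unc (28 of 94, adjusted p = 8.49e-08), lin (13 of 46, 0.0046), cpr (5 of 8, 0.0113), nhr (38 of 254, 0.0113), dpy (8 of 24, 0.0203), sup (5 of 10, 0.0262) and egl (8 of 26, 0.0294). The nuclear hormone receptor family nhr included nhr-202 at 2.58 ± 0.26, nhr-101 at 2.39 ± 0.37 and nhr-98 at 2.24 ± 0.23, with 3 members lower. In the lin family, lin-42, a period homolog of the developmental clock, rose by 3.18 ± 0.36 and the Hox gene lin-39 by 2.07 ± 0.33 (adjusted p = 0.0515 without PVD and OLL replicate 2). In the cpr family of cathepsin B-like proteases, cpr-1, cpr-4 and cpr-5 rose by 2.09, 2.08 and 1.99, with the cpr-4 call lost without PVD and OLL replicate 1 or 2 (adjusted p up to 0.0677). Families enriched among lower genes were col (69 of 128, 4.08e-55), msp (23 of 23, 3.97e-29), his (13 of 26, 4.04e-09), ssp (4 of 8, 0.0164) and ttr, the transthyretin-related genes (8 of 40, 0.0203). Members of a family are not independent, and those of col, msp and his can share probes. The medians of the collagen and histone lists turned positive with centring on the bioB and bioC controls, while camera still placed both below the other genes.

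The molting regulator nhr-23 was 1.65 ± 0.30 higher (limma, adjusted p = 0.014, lost without PVD and OLL replicate 1 or 2, up to 0.0592), and the adult collagen gene col-19 was lower by -2.92 ± 0.62 (adjusted p = 0.0231, lost without PVD and OLL replicate 1 or 2 or whole animal replicate 1, up to 0.0887). Whole animal replicate 3 had the highest signals of col-19 (7.96, against 5.94 and 5.28 on the other reference arrays), vit-2 (9.98, against 7.06 and 7.15) and vit-6 (9.88, against 7.15 and 6.67), and the lowest of dpy-8 (3.55, against 4.19 and 4.99).

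Control probe sets differed between groups. The 32 no-target controls had a median difference of -0.50, with 10 lower and 0 higher (limma, adjusted over the controls), and the 10 bioB and bioC hybridisation control probe sets had a median of -1.23, all 10 lower. The other 8 hybridisation controls (bioD and cre) had a median of -0.31, ranging from -1.53 to -0.02, with 1 lower and 0 higher. The 3' minus 5' difference of the worm controls was 1.60 larger in the PVD and OLL samples for catalase and 0.43 larger for actin, and it changed by -0.36 for Gapdh, 0.19 for gly14 and -0.08 for ubiquitin.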
